A study of Homo sapiens with 12 samples.

How the data were processed

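RNA levels were measured in 12 cultures of the CCRF-CEM line, 3 biological replicates each of untreated cells and of cells treated for 3 h with AB61, tubercidin or actinomycin D at 5 times the IC50. Per the labels' protocols, cells grew in RPMI with 10% serum, RNA was extracted with Trizol, and 200 ng of total RNA was labelled as biotinylated cDNA for whole-transcript arrays. No vehicle is described for the untreated cultures. Per the submitters' processing notes, the authors used RMA, oligo and limma, in versions not given in the sources used here. The deposited level values are log2 RMA values per transcript cluster, 22011 probe sets on each array. The authors' comparison tables hold group means, headed intensity per the file headers but on the log2 scale from the values, and log2 fold changes equal to the differences of those means. They also hold an unadjusted p-value per probe set and no adjusted one, and which samples entered the authors' limma fit is not stated in the sources used here. Their p-values correspond to 13.4 degrees of freedom if the standard errors were equal, against 11.3 in the fit made here on all probe sets, so their samples or settings differed from that fit.

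Gene names came from the annotation supplied with the series. Of the probe sets, 14432 carried exactly 1 gene symbol, 2408 carried several and 5171 were not listed. The probe sets with 1 symbol were used, the brightest by mean level over the 12 arrays where a gene had several (197 genes), giving 14232 genes. The others were tested as probe sets and no gene was named from them. No filter on dim genes was applied, since no detection calls or background values were used here. RMA gives the arrays similar distributions, so a loss of mRNA common to all genes cannot be seen in these values. Array correlations ranged from 0.983 to 0.996, and the smallest median absolute difference between any pair of arrays was 0.0925, so no array was a copy of another. The median standard error of a log2 fold change was 0.13, and its 95% interval reached 0.28 to either side in the median.

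Linear models were fitted in limma 3.58.1 under R 4.3.3 on all 12 arrays and 4 groups, with eBayes without trend or robust settings (8 residual and 4.91 prior degrees of freedom). Of 6 contrasts, 3 set a treatment against control and 3 set treatments against each other, with two-sided p-values adjusted by the Benjamini-Hochberg method over the genes of each contrast and a threshold of 0.05. Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, and adjusted over the 27 of 32 lists that had at least 5 measured genes. The lists, comparisons, tests and rule for naming genes were chosen before the data were examined. For each treatment the rule named up to 8 genes per direction with the largest change among those past the threshold with full separation of the arrays. It added members with the largest changes from each list described, at most 4 past the threshold or otherwise 2, and 14 regulators named in advance. Of these 14, MCL1 had no probe set with a single symbol, and 1 other is not reported here. In direct contrasts no gene passed, and the genes named there, as well as CMAHP and those of the pooled comparison, were chosen after their values were seen.

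Correlations and overlaps of treatments were set against 100 simulations of unchanged groups that share the control arrays, with a fixed seed. These simulations drew each gene independently. The replicate number was tested as a pairing by correlating each array's deviations from its group mean with those of the array of the same number. For control and AB61 these correlations were 0.158, 0.355 and 0.268. Each other pair of groups had at least 1 value under 0.1, the lowest being -0.194 for AB61 and tubercidin replicate 2. The number was therefore read as a pairing for AB61 and control alone, although 11 of the 12 arrays correlated best with an array of their own number. The main fits held no term for the number, also for AB61 and control. Any effect common to arrays of the same number therefore stays in their residual spread and can hide differences. The method was tested on simulated data with the same number of arrays, where changes of 1 on the log2 scale were recovered in 89.6%, 86.6% and 88.1% of genes for AB61, tubercidin and actinomycin D, changes of 0.5 in 43.3%, 31.3% and 32.8%, and 4.32%, 4.61% and 6.37% of calls were false. A simulated list shift of -0.3 was found, with 0 of the other lists called. The simulated genes and arrays were independent. These rates therefore do not cover genes that vary together or differences between arrays, and do not give the false calls in the real data.

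Alternatives covered the scaling of arrays, a filter on dim genes, the variance model, array weights, the samples in the fit, the replicate block, the choice of probe set, the list test and each array left out in turn. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9. Splicing and exon-level signals were not analysed here, and lists of small noncoding and mitochondrially encoded RNAs could not be tested because fewer than 5 of their genes had a usable probe set.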

Results

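The series measured mRNA levels in CCRF-CEM cells, a human T-lymphoblastic leukaemia line, after short exposure to 3 cytostatic compounds. AB61 is 7-(2-thienyl)-7-deazaadenosine, tubercidin is the parent 7-deazaadenosine, and actinomycin D is a DNA-binding inhibitor of transcription. Cultures received AB61 at 250 nM, tubercidin at 550 nM or actinomycin D at 1 nM for 3 h, in each case 5 times the IC50. Untreated cultures served as the control. No vehicle is described for them, so changes against control cannot be told apart from an effect of a vehicle. Each of the 4 groups held 3 arrays described as biological replicates, 12 arrays in all, and levels are given as log2 RMA values over 14232 genes. The median level per array lay between 6.58 on AB61 replicate 3 and 6.69 on AB61 replicate 2, and correlations between arrays ranged from 0.983 to 0.996. The lowest of all pairs was between AB61 replicates. The median SD of a gene among replicates was 0.13 in control, 0.19 in AB61, 0.13 in tubercidin and 0.11 in actinomycin D, and with 3 arrays per group the number of arrays limits the precision. The series asked which genes were differentially expressed after each treatment, and the treatments were also compared with each other.

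AB61 lowered FOSL2, which encodes the Fra-2 subunit of the AP-1 transcription factor, 2.65-fold, from 9.28 ± 0.40 in control to 7.88 ± 0.11 (SD, n = 3; log2 fold change -1.40, SE 0.18, adjusted p = 0.0166). The stress-induced transcription factor gene ATF3 was 1.80-fold lower (-0.85, SE 0.15, adjusted p = 0.0493), and CORO2A, a coronin family gene, was 1.89-fold lower (-0.92, SE 0.15, adjusted p = 0.0346). EFNB2, which encodes the membrane ligand ephrin-B2, fell by 0.73 and VEGFA, the vascular endothelial growth factor A gene, fell by 0.63 on the log2 scale. Among the genes that rose, CHRNA6, a nicotinic acetylcholine receptor subunit gene, went from 6.25 ± 0.08 to 7.20 ± 0.11 (1.94-fold, SE 0.12 on the log2 scale, adjusted p = 0.0166), and the serpin gene SERPINB8 from 7.77 ± 0.08 to 8.66 ± 0.20 (1.85-fold, adjusted p = 0.0346).

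In all, 24 of 14232 genes passed an adjusted p of 0.05 after AB61, 13 higher and 11 lower, and 1 of them, FOSL2, changed at least 2-fold. The others named on the higher side were CNGA1, a cyclic nucleotide-gated channel gene (0.97, SE 0.15), the B7 family gene HHLA2 (0.79, SE 0.12), RHBDD2 (0.73, SE 0.11), the zinc finger gene ZNF583 (0.70, SE 0.12), the transcription factor gene RUNX2 (0.66, SE 0.10) and SPMIP4 (0.64, SE 0.10). On the lower side they were GKAP1 (-0.92, SE 0.16), the nuclear anchoring protein gene AKAP8L (-0.85, SE 0.14) and HAGH, which encodes glyoxalase II (-0.75, SE 0.13). Their adjusted p-values lay between 0.0346 and 0.0493. At an unadjusted p below 0.05, 1718 genes (12.1%) differed, and 12.6% of genes had all 3 AB61 arrays beyond all 3 control arrays. Chance gives 10% if arrays are exchangeable. Arrays that share a replicate number need not be, so the 10% here and below is not an exact reference.

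Gene lists fixed before the data were examined moved mostly downward after AB61. Cholesterol synthesis genes were lower by list median (-0.32, 0 of 13 fitted above 0, adjusted p = 1.87e-05), and the estimate ended the call (adjusted p = 0.224 with an estimated correlation). No member passed over all genes and 2 passed adjusted over the list alone, both lower. INSIG1, a regulator of sterol sensing, stood at -0.71 (SE 0.14, adjusted p = 0.0592) and HMGCS1, a cytosolic HMG-CoA synthase gene, at -0.74 (SE 0.19, adjusted p = 0.143). Without AB61 replicate 1 the cholesterol median was -0.19. Heat shock protein genes were lower by -0.31 in the median (10 of 11 fitted below 0, 3 lower adjusted over the list alone, adjusted p = 1.48e-05; adjusted p = 0.137 with an estimated correlation), with HSPA4L at -0.70 (SE 0.19) and HSPE1 at -0.66 (SE 0.21). Replication-dependent histone genes were lower by -0.30 (47 of 50 fitted below 0, 2 lower adjusted over the list alone, adjusted p = 2.12e-14; adjusted p = 0.382 with an estimated correlation), with H2AC12 at -0.88 (SE 0.34; -0.49 without AB61 replicate 2) and H1-5 at -0.81 (SE 0.26). The histone median was -0.52 on AB61 replicate 2, -0.22 on replicate 1 and -0.14 on replicate 3, and -0.19 in the fit without replicate 2. These genes have near-identical copies that the probe sets cannot fully separate.

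Immediate early and short-lived regulator genes were lower after AB61 by a list median of -0.20 (21 of 26 fitted below 0, adjusted p = 5.68e-06; adjusted p = 0.382 with an estimated correlation). ATF3 passed over all genes, and 6 members, all lower, passed adjusted over the list alone. The nuclear receptor gene NR4A1 stood at -1.79 (SE 0.37, adjusted p = 0.0768), and EGR1, a zinc finger transcription factor gene, at -1.66 (SE 0.54, adjusted p = 0.234; -0.82 without control replicate 3). EGR1 spread from 7.49 to 10.69 across the control arrays and from 7.29 to 7.43 across the AB61 arrays. The list median of control replicate 1, -0.29 against the mean of the controls, lay below that of each AB61 array. The list median in the fit was -0.33 without control replicate 1 and -0.13 without control replicate 3. SR splicing factor and CLK kinase genes were also lower (-0.25, adjusted p = 1.87e-05; adjusted p = 0.382 with an estimated correlation), with 2 of 16 lower adjusted over the list alone, CLK3 at -0.61 (SE 0.21; -0.35 without control replicate 3) and TRA2A at -0.59 (SE 0.17). Their median was -0.16 without AB61 replicate 1.

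The remaining 5 lists that shifted after AB61 did so by smaller medians, and each lost its call without at least 1 array. They were the genes of the nuclear-encoded respiratory chain (-0.15, adjusted p = 4.37e-05; adjusted p = 0.504 with an estimated correlation), of the RNA polymerase II machinery (-0.16, 0.00122; adjusted p = 0.472 with an estimated correlation), of the cytosolic ribosomal proteins (-0.17, 0.0157; adjusted p = 0.525 with an estimated correlation), of DNA replication and S phase (-0.09, 0.0237; adjusted p = 0.504 with an estimated correlation) and of the ATF4 and integrated stress response (-0.19, 0.0436; adjusted p = 0.382 with an estimated correlation). Within the last list ATF3 passed over all genes, 3 members higher and 6 lower passed adjusted over the list alone, and DDIT4, an inhibitor of mTORC1 signalling, stood at -1.30 (SE 0.26, adjusted p = 0.0739). Without AB61 replicate 2 all 5 calls ended, at adjusted p = 0.069, 0.258, 0.206, 0.715 and 0.222 in the order given, with medians of -0.082, -0.093, -0.11, -0.021 and -0.14. Without control replicate 1 the ribosomal protein and S phase calls ended (adjusted p = 0.212 and 0.149), and the ATF4 call ended without control replicate 3 (0.180) or AB61 replicate 1 (0.106). Without control replicate 1 the ribosomal protein and S phase medians were -0.080 and -0.027, and without control replicate 3 the ATF4 median was -0.11 and the respiratory chain median -0.24. Of 27 lists tested, 10 shifted, all lower, and 0 did so with an estimated correlation or with fry, the self-contained set test of limma. The number that shifted was 6 without AB61 replicate 2, 6 after repeated quantile normalization and 6 with the intensity trend removed.

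The number of genes that passed after AB61 rested on which arrays entered the fit. It was 9, 0 and 0 without control replicates 1, 2 and 3, and 0, 0 and 98 without AB61 replicates 1, 2 and 3. Arrays of the other treatments, which enter through the common variance, mattered as well, with 5, 2 and 3 genes without actinomycin D replicates 1, 2 and 3, and 23, 30 and 2 without tubercidin replicates 1, 2 and 3. The number changed at least 2-fold was 6, 0 and 0 without control replicates 1, 2 and 3, and 0, 0 and 12 without AB61 replicates 1, 2 and 3. The replicate numbers paired the AB61 and control arrays, and with the number as a block 193 genes passed, 87 higher and 106 lower, in a fit of all 12 arrays. With the block in a fit of AB61 and control alone 11 passed, 2 higher and 9 lower. P-values printed for single genes are from fits without the block. With the block in all 12 arrays 18 values of named genes, over all contrasts, newly passed and 0 lost their call. With the block in fits of 2 groups these were 5 and 35. With each array centred on its median 2 genes were higher and 1 lower, and after repeated quantile normalization 22 were higher and 12 lower. With each array's trend on intensity removed 13 were higher and 5 lower. Centring each array on its ribosomal protein genes shifted the median of all genes to -0.14 and left 0 higher and 14 lower, so directions are relative to the deposited scaling.

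**Figure D1:**
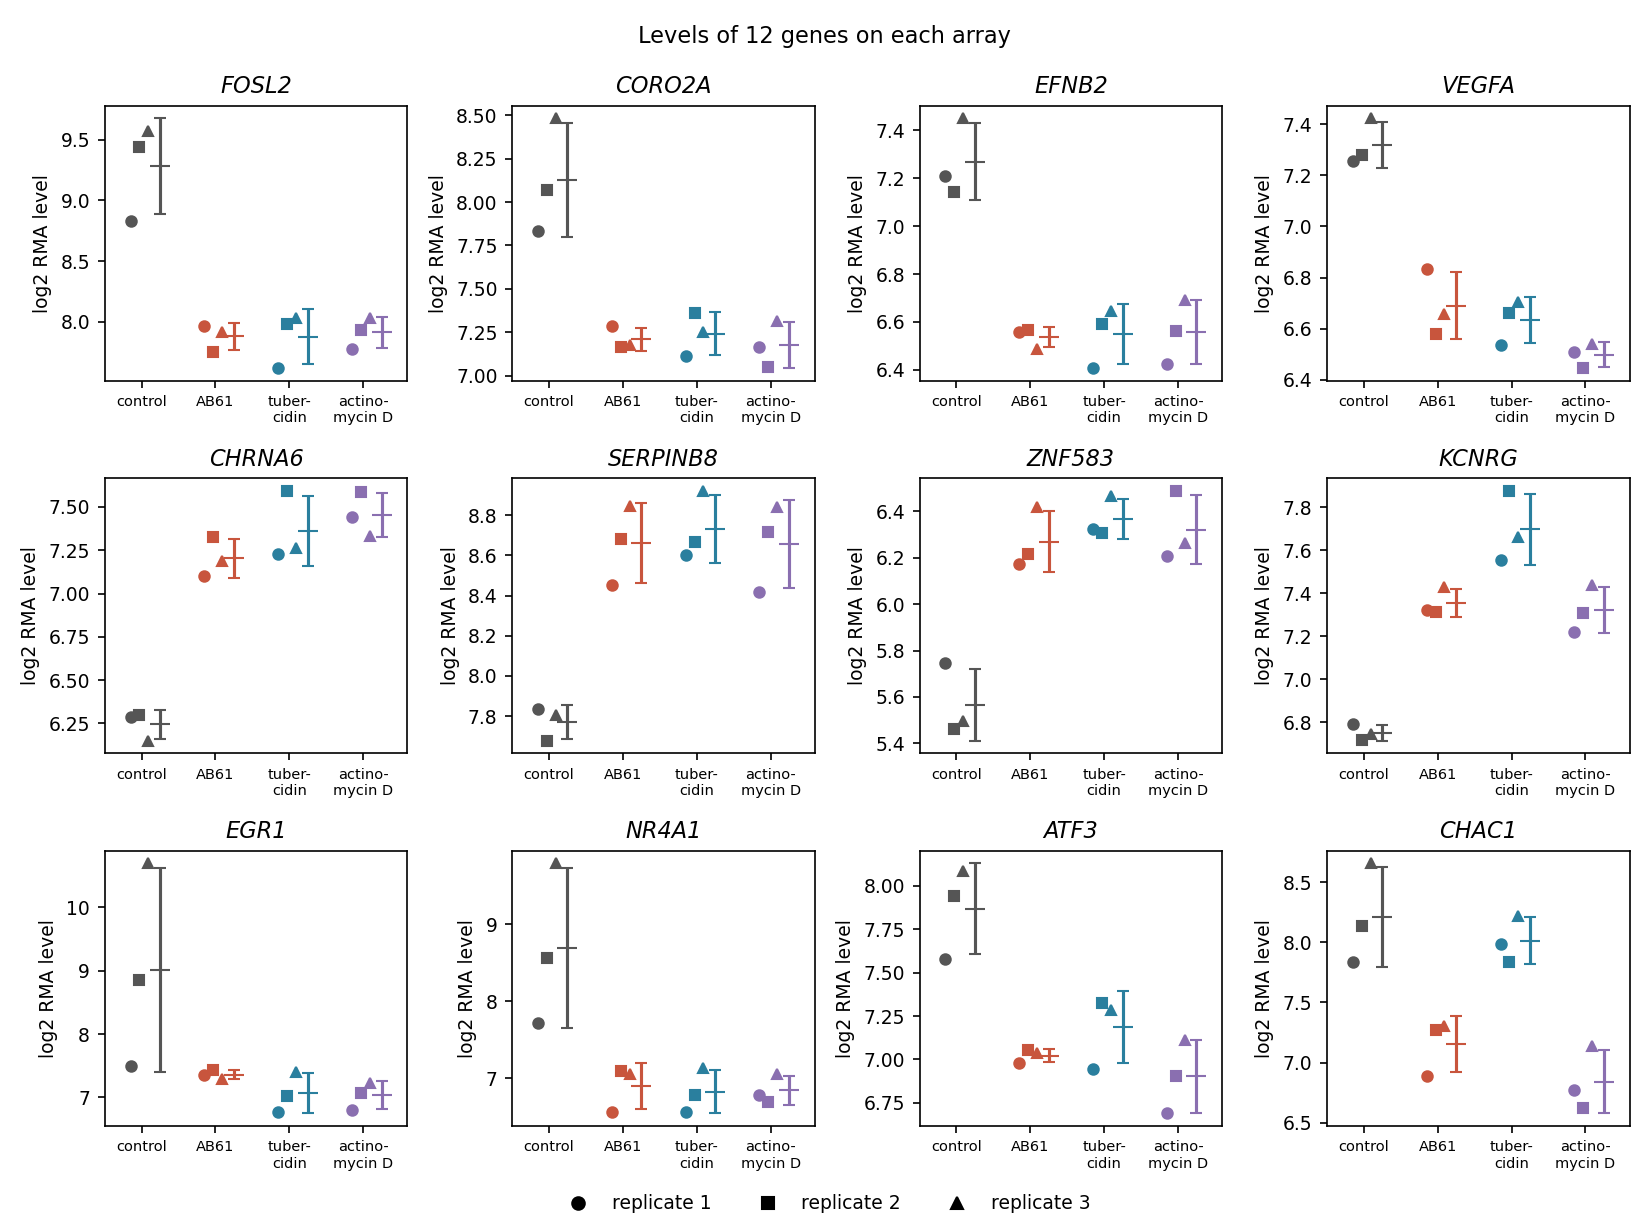
Levels of 12 genes on each array, as log2 RMA values, for the control, AB61, tubercidin and actinomycin D groups; symbols mark the replicate number, and the horizontal tick and bar give the group mean and SD (n = 3). FOSL2 means were 9.28 in control, 7.88 in AB61, 7.88 in tubercidin and 7.91 in actinomycin D, and EGR1 spread from 7.49 to 10.69 within the control group.

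Tubercidin lowered FOSL2 to 7.88 ± 0.23 (2.65-fold lower, log2 fold change -1.40, SE 0.18, n = 3, adjusted p = 0.00826). MBD5, a methyl-CpG-binding domain gene, was 1.86-fold lower (-0.90, SE 0.12, adjusted p = 0.0185), CORO2A 1.85-fold lower (-0.89, SE 0.15, adjusted p = 0.0438), and EFNB2 and VEGFA fell by 0.72 and 0.68 (SE 0.11 and 0.10). CHRNA6 rose 2.17-fold to 7.36 ± 0.20 (1.11, SE 0.12, adjusted p = 0.00404), SERPINB8 rose 1.94-fold (0.96, SE 0.14, adjusted p = 0.0185), and KCNRG, a potassium channel regulator gene, rose 1.93-fold from 6.75 ± 0.04 to 7.70 ± 0.16 (0.94, SE 0.10, adjusted p = 0.00404). FANCF, a gene of the Fanconi anaemia core complex, was 1.77-fold higher (0.82, SE 0.12), ZNF583 1.74-fold (0.80, SE 0.12), the P4-ATPase gene ATP10D 1.65-fold (0.72, SE 0.11) and KIAA0753 1.62-fold (0.69, SE 0.11).

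After tubercidin 13 genes passed, 8 higher and 5 lower, of which CHRNA6 and FOSL2 changed at least 2-fold. At an unadjusted p below 0.05, 1253 genes (8.80%) differed, and 14% of genes had fully separated arrays against 10% by chance. Immediate early and short-lived regulators shifted down as a list (median -0.29, 25 of 26 fitted below 0, adjusted p = 4.66e-10; adjusted p = 0.396 with an estimated correlation), with 0 members past the test over all genes and 7 lower adjusted over the list alone. NR4A1 stood at -1.87 (SE 0.37, adjusted p = 0.0929) and EGR1 at -1.94 (SE 0.54, adjusted p = 0.217), or -1.11 without control replicate 3, and the list median of control replicate 1 fell within the range of the tubercidin arrays, which ran from -0.39 to -0.15. ZNF zinc finger genes shifted up under the deposited scaling, though down to -0.10 under ribosomal protein centring (median 0.08, 202 of 305 fitted above 0, 1 higher over all genes and 3 adjusted over the list alone, adjusted p = 7.5e-07; adjusted p = 0.325 with an estimated correlation). ZNF583 was the member that passed, and ZNF616 stood at 0.98 (SE 0.24, adjusted p = 0.177).

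Heat shock protein genes were lower after tubercidin (median -0.21, adjusted p = 0.0184; adjusted p = 0.396 with an estimated correlation), as were histone genes (-0.11, 36 of 50 fitted below 0, 0.0208; adjusted p = 0.946 with an estimated correlation), with 0 members of either list past the test over all genes or adjusted over the list alone. HSPA4L stood at -0.54 (SE 0.19), HSPE1 at -0.52 (SE 0.21), H2BC21 at -0.70 (SE 0.34) and H3C1 at -0.50 (SE 0.18). HSPA4L was -0.34 without control replicate 3 and H2BC21 -0.36 without tubercidin replicate 1. DNA damage response and homologous recombination genes were higher except under ribosomal protein centring, -0.03 (median 0.15, 3 of 16 higher adjusted over the list alone, 0.0184; adjusted p = 0.769 with an estimated correlation), with the BRCA1-associated helicase gene BRIP1 at 0.66 (SE 0.17) and the BRCA2 partner gene PALB2 at 0.52 (SE 0.11). Mitosis genes were higher by 0.11, against -0.07 under ribosomal protein centring (16 of 22 fitted above 0, 0.0229; adjusted p = 0.927 with an estimated correlation), with PLK1 at 0.34 (SE 0.09) and KIF11 at 0.33 (SE 0.22), or 0.15 without tubercidin replicate 3. Without tubercidin replicate 3 the heat shock, histone, DNA damage and mitosis calls ended, at adjusted p = 0.063, 0.560, 0.177 and 0.269, with medians of -0.14, -0.022, 0.051 and 0.050. The heat shock call also ended without control replicate 3 (0.107), the histone call without control replicate 1 (0.247) or tubercidin replicate 1 (0.334), the DNA damage call without control replicate 2 (0.165), and the mitosis call without control replicate 2 (0.0864) or tubercidin replicate 2 (0.0555). Without tubercidin replicate 2 the histone median was -0.23 and the DNA damage median 0.23, and without control replicate 2 the DNA damage median was 0.075. Of 27 lists 6 shifted, 3 lower and 3 higher, and 0 did so with an estimated correlation or with fry.

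Without control replicates 1, 2 and 3 the tubercidin count was 33, 2 and 3, and without tubercidin replicates 1 and 3 it was 4 in both fits. Without 1 array of the other treatments it lay between 10 and 20. The number changed at least 2-fold was 14, 1 and 1 without control replicates 1, 2 and 3. The split of 8 higher and 5 lower became 7 and 2 after repeated quantile normalization and 5 and 1 with the intensity trend removed. With ribosomal protein centring, which shifted the median of all genes to -0.20, it became 1 and 3.

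Actinomycin D lowered CHAC1, a gamma-glutamylcyclotransferase gene induced by ATF4, 2.58-fold, from 8.21 ± 0.42 to 6.84 ± 0.27 (log2 fold change -1.37, SE 0.20, n = 3, adjusted p = 0.0345), and FOSL2 2.58-fold to 7.91 ± 0.13 (-1.37, SE 0.18, adjusted p = 0.0146). ATF3 was 1.95-fold lower (-0.97, SE 0.15, adjusted p = 0.0345), CORO2A 1.94-fold (-0.95, SE 0.15, adjusted p = 0.0345), VEGFA 1.77-fold (-0.82, SE 0.10, adjusted p = 0.0118) and CEBPB, a bZIP transcription factor gene, 1.52-fold (-0.60, SE 0.10, adjusted p = 0.0378). MBD5 and EFNB2 fell by 0.75 and 0.71 (SE 0.12 and 0.11). CHRNA6 rose 2.31-fold to 7.45 ± 0.13 (1.21, SE 0.12, adjusted p = 0.00222) and SERPINB8 1.85-fold (0.88, SE 0.14, adjusted p = 0.0345). ZNF583 (0.75, SE 0.12), FANCF (0.74, SE 0.12), ATP10D (0.68, SE 0.11), the mRNA decapping cofactor gene DCP1B (0.68, SE 0.12), the prostaglandin D2 receptor gene PTGDR (0.62, SE 0.10) and the BBSome gene TTC8 (0.50, SE 0.08) were also higher.

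After actinomycin D 17 genes passed, 9 higher and 8 lower, and 3 changed at least 2-fold, CHRNA6 upward and CHAC1 and FOSL2 downward. At an unadjusted p below 0.05, 1336 genes (9.39%) differed, and 14.4% of genes had fully separated arrays against 10% by chance. Immediate early and short-lived regulators shifted down (median -0.31, 23 of 26 fitted below 0, adjusted p = 3.13e-10; adjusted p = 0.331 with an estimated correlation), with ATF3 past the test over all genes and 5 lower adjusted over the list alone. NR4A1 stood at -1.85 (SE 0.37, adjusted p = 0.101) and EGR1 at -1.97 (SE 0.54, adjusted p = 0.209), and without control replicate 3 EGR1 was -1.13 and the list median -0.21. The median of control replicate 1, -0.29, lay within the range of the actinomycin D arrays, -0.37 to -0.24. ATF4 and integrated stress response genes shifted down (median -0.18, adjusted p = 0.00151; adjusted p = 0.331 with an estimated correlation), and this list was the 1 that fry called (adjusted p = 0.0486). CHAC1, ATF3 and CEBPB passed over all genes, and 9 lower and 3 higher passed adjusted over the list alone. Its array medians lay between -0.26 and -0.22 in actinomycin D and between -0.03 and 0.06 in control.

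Heat shock protein genes (median -0.22, 10 of 11 fitted below 0, adjusted p = 0.00283; adjusted p = 0.331 with an estimated correlation) and histone genes (-0.16, 41 of 50 fitted below 0, 2.19e-05; adjusted p = 0.74 with an estimated correlation) were lower after actinomycin D, with 0 members past the test over all genes or adjusted over the list alone. HSPE1 stood at -0.57 (SE 0.21), HSPA4L at -0.49 (SE 0.19, or -0.29 without control replicate 3), H1-5 at -0.69 (SE 0.26) and H3C1 at -0.64 (SE 0.18). SR splicing factor and CLK kinase genes (-0.18, 0.00283; adjusted p = 0.489 with an estimated correlation) included CLK3 at -0.57 (SE 0.21, or -0.31 without control replicate 3) and TRA2A at -0.51 (SE 0.17), and the call ended without actinomycin D replicate 1 (adjusted p = 0.106). Respiratory chain genes (-0.12, 0.00266; adjusted p = 0.74 with an estimated correlation) lost their call without control replicate 1 (0.0884), at a median of -0.053, and the median was -0.20 without control replicate 3 and -0.06 without actinomycin D replicate 3. Genes of the RNA polymerase II machinery (-0.13, 0.0377; adjusted p = 0.74 with an estimated correlation) lost theirs without control replicate 1 (0.110), control replicate 3 (0.0707) or actinomycin D replicate 1 (0.158).

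Endoplasmic reticulum chaperone and unfolded protein response genes were lower (median -0.06, 3 of 15 lower adjusted over the list alone, adjusted p = 0.0242; adjusted p = 0.489 with an estimated correlation), led by HERPUD1 at -1.11 (SE 0.22, adjusted p = 0.0983) and DNAJB9 at -0.53 (SE 0.14). Without actinomycin D replicate 1 the call ended (0.148) at a median of -0.11, and the median was -0.15 without control replicate 3 and -0.13 without actinomycin D replicate 2. TGF-beta and BMP early targets (-0.12, 0.0397; adjusted p = 0.419 with an estimated correlation), with ID1 at -0.55 (SE 0.16) and ID2 at -0.68 (SE 0.32, from -1.04 without control replicate 1 to -0.26 without control replicate 3), lost the call without control replicate 3 (0.256) or actinomycin D replicates 2 (0.0562) or 3 (0.0706). Cytokine and growth factor feedback inhibitors (-0.12, 0.0475; adjusted p = 0.736 with an estimated correlation), with SPRY2 at -0.35 (SE 0.18, from -0.52 without control replicate 2 to -0.11 without control replicate 3), lost it without control replicate 3 (0.654) or actinomycin D replicates 1 (0.316) or 2 (0.0562). Their median was -0.23, -0.08 and -0.08 without control replicates 1, 2 and 3, and -0.06 and -0.20 without actinomycin D replicates 1 and 3. ZNF genes were higher by 0.04, against -0.21 under ribosomal protein centring (0.00583; adjusted p = 0.489 with an estimated correlation). That call ended without actinomycin D replicate 3 (0.384), at a median of 0.02. Mitosis genes were higher by 0.07, against -0.19 under ribosomal protein centring (0.0397; adjusted p = 0.74 with an estimated correlation), with PLK1 at 0.37 (SE 0.09). That call ended without control replicates 1 (0.0697) or 2 (0.146) or actinomycin D replicates 2 (0.0593) or 3 (0.646). The mitosis median was 0.12 without control replicate 3, 0.22 without actinomycin D replicate 1 and 0.01 without actinomycin D replicate 3. Of 27 lists 12 shifted, 10 lower and 2 higher, 0 with an estimated correlation and 1 with fry.

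Without control replicates 1, 2 and 3 the actinomycin D count was 25, 1 and 1, and without actinomycin D replicates 1, 2 and 3 it was 1, 1 and 4. Without AB61 replicates 1, 2 and 3 it was 4, 3 and 20, and without tubercidin replicates 1, 2 and 3 it was 3, 18 and 3. The number changed at least 2-fold was 14, 1 and 1 without control replicates 1, 2 and 3, and 1 and 1 without actinomycin D replicates 1 and 2. The split of 9 higher and 8 lower became 1 and 2 with the intensity trend removed and 1 and 1 with each array centred on its median. It became 66 and 64 with the replicate block and 298 and 241 with array weights. With ribosomal protein centring, which shifted the median of all genes to -0.25, the split became 1 and 34.

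Several regulators of transcription and stress named in advance did not pass in any of these 3 comparisons in the fit without the replicate block. MYC, which encodes a short-lived transcription factor, stood at 0.19 after AB61, 0.16 after tubercidin and 0.25 after actinomycin D (SE 0.36), with an SD of 0.78 among control arrays. CDKN1A, a cyclin-dependent kinase inhibitor gene (-0.09, -0.22 and -0.06, SE 0.11), and the ubiquitin ligase gene MDM2 (0.38, 0.32 and 0.40, SE 0.16), in the same order of treatments, also missed the threshold, as did FOS (-0.37, -0.40 and -0.42, SE 0.15) and JUN (-0.27, -0.14 and -0.29, SE 0.13). HEXIM1, whose protein inhibits the elongation kinase P-TEFb, stood at -0.78, -0.74 and -0.64 (SE 0.16, adjusted p = 0.0768, 0.129 and 0.183). Its level rose with the replicate number in each group, in control from 8.28 to 8.64 and in AB61 from 7.51 to 7.92. That rise widens the residual spread in a fit without the block. ID1 stood at -0.63, -0.56 and -0.55 (SE 0.16), DDIT3 at -0.34, 0.06 and -0.59 (SE 0.20), HES1 at -0.12, -0.16 and -0.12 (SE 0.18), and the adenosine kinase gene ADK at -0.29, -0.09 and -0.19 (SE 0.14). After tubercidin ATF3 stood at -0.68 (SE 0.15, adjusted p = 0.129).

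Direction changed without 1 array for 5 of these regulators. MYC stood at -0.25, -0.27 and -0.18 without control replicate 3, at -0.035 after AB61 without AB61 replicate 1, and at -0.018 after actinomycin D without actinomycin D replicate 1. After tubercidin DDIT3 stood at -0.14 without tubercidin replicate 2 and -0.056 without control replicate 1, and ADK at 0.016 without tubercidin replicate 3 and 0.0087 without control replicate 1. CDKN1A stood at 0.033 after AB61 without AB61 replicate 3, and HES1 at 0.040 after actinomycin D without actinomycin D replicate 3. Others kept direction at a smaller size. Without control replicate 3 FOS stood at -0.18, -0.22 and -0.24 and JUN at -0.15, -0.034 and -0.18 after AB61, tubercidin and actinomycin D. HES1 stood at -0.021 after AB61 without control replicate 1 and -0.042 after tubercidin without tubercidin replicate 3. DDIT3 stood at -0.17 after AB61 without AB61 replicate 1, MDM2 at 0.17 after tubercidin without tubercidin replicate 3, and ADK at -0.19 after AB61 and -0.092 after actinomycin D without control replicate 1. Markers of other cell lineages had list medians of 0.11, -0.04 and 0.06 (adjusted p = 0.307, 0.824 and 0.528).

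**Figure D2:**
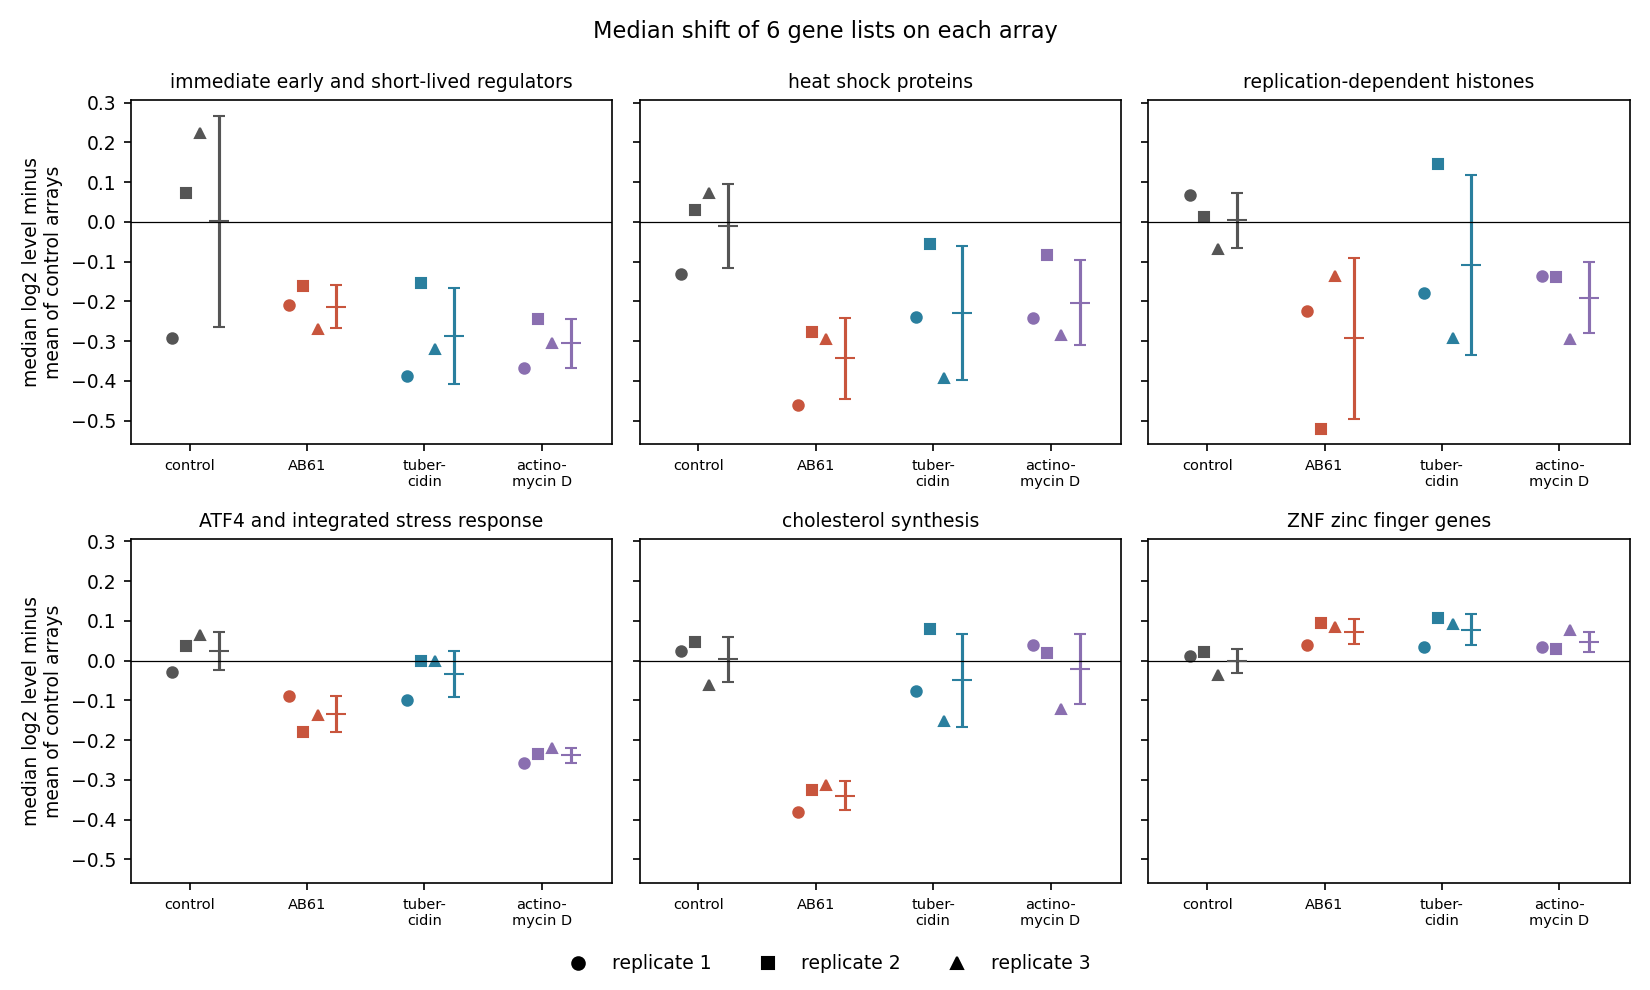
Median shift of 6 gene lists on each array, as log2 level minus the mean of the control arrays, for the control, AB61, tubercidin and actinomycin D groups; symbols mark the replicate number, and the tick and bar give the mean and SD of the array medians (n = 3). Cholesterol synthesis genes lay between -0.38 and -0.31 on the AB61 arrays, and the immediate early median of control replicate 1 was -0.29.

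The genes that passed against control overlapped between the compounds. All treatments were set against the same untreated cultures, so a common change need not be a response to the compounds. Of 30 genes that passed in any comparison with control, 8 passed in all 3, with CHRNA6, SERPINB8, ZNF583 and the pseudogene CMAHP higher and FOSL2, CORO2A, EFNB2 and VEGFA lower, and for all 8 the 9 treated arrays lay beyond the 3 control arrays. AB61 and tubercidin shared 10 genes in the same direction, AB61 and actinomycin D 11, and tubercidin and actinomycin D 11, with 0 opposite. Independent lists would share 0.00731, 0.00822 and 0.00506 higher genes and 0.00386, 0.00618 and 0.00281 lower genes, values that leave out the shared controls. Simulated unchanged groups sharing the controls had at most 0, 1 and 0 genes in common, values that leave out the effects. The excess over either therefore does not measure a shared effect, and part of it may come from the shared controls. Without control replicates 2 or 3 these overlaps were 0, 0 and 1, and without AB61 replicates 1 or 2 those with AB61 were 0. Without tubercidin replicates 1 and 3 the overlaps of AB61 and tubercidin were 3 and 2, and those of tubercidin and actinomycin D 1 and 2. Without actinomycin D replicates 1, 2 and 3 the overlaps were 1, 1 and 2 with AB61 and 1, 1 and 3 with tubercidin, and without control replicate 1 that of tubercidin and actinomycin D was 19.

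Across genes, the log2 changes of AB61 and tubercidin correlated at r = 0.66, those of AB61 and actinomycin D at 0.81 and those of tubercidin and actinomycin D at 0.79. Simulated unchanged groups of equal spread sharing the controls gave a median of 0.50. The covariances were 0.0268, 0.0336 and 0.0289 against simulated medians of 0.0132, 0.0132 and 0.0134, differences of 0.0136, 0.0204 and 0.0155. Genes are not independent replicates, and with 3 control arrays the controls could not be split into parts of 2 or more, so part of the excess may come from the shared controls. Without AB61 replicate 3 the AB61 and tubercidin correlation was 0.435.

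**Figure D3:**
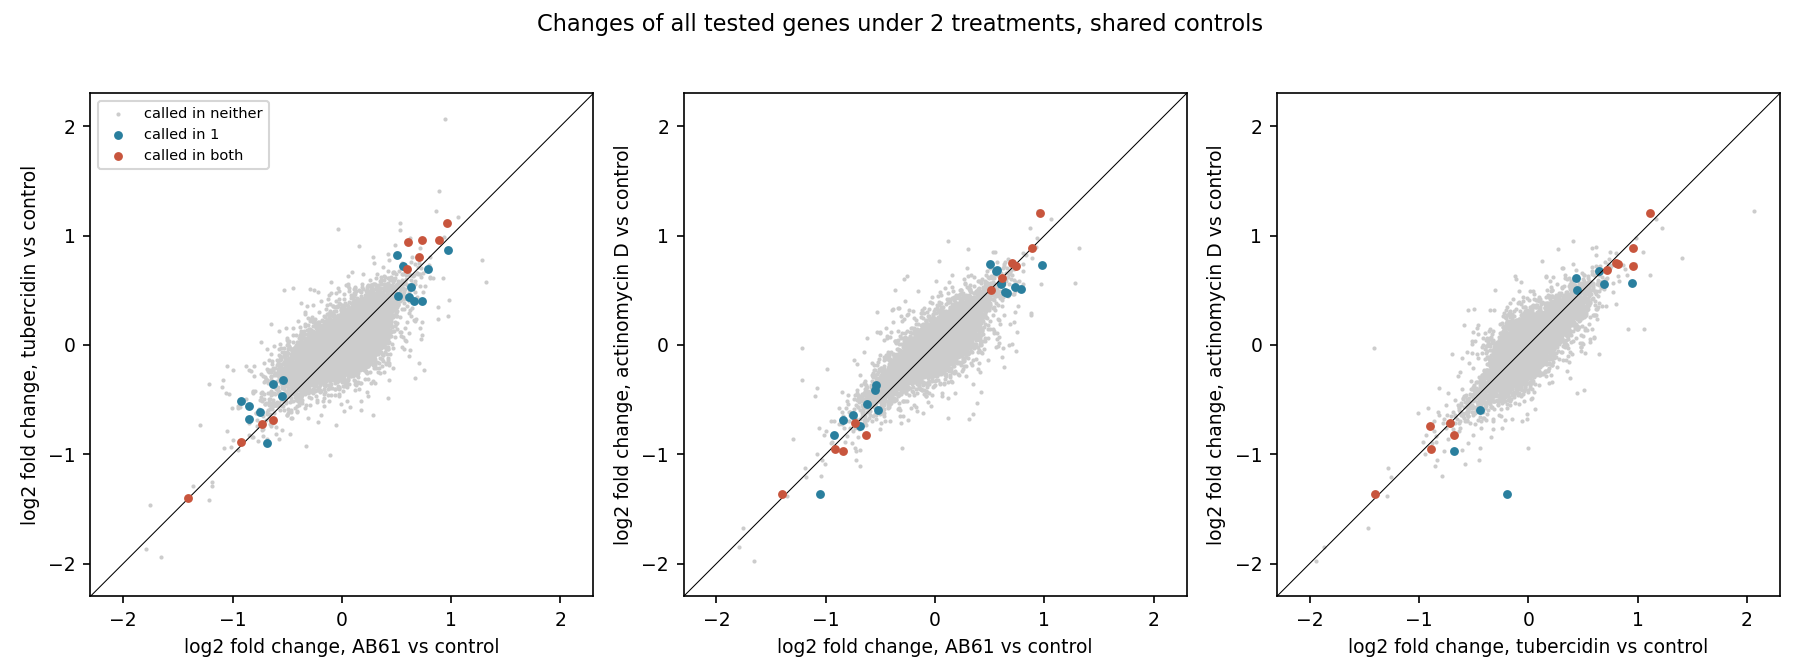
Log2 fold changes against control of all 14232 genes for each pair of treatments, with 1 point per gene, coloured by the comparisons in which it passed an adjusted p of 0.05; the line marks equal changes. The same 3 control arrays enter both axes, and r was 0.66, 0.81 and 0.79 from left to right.

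Compared directly, the nucleosides AB61 and tubercidin, which differ by the 2-thienyl group at position 7 and were given at different molar doses, had a FOSL2 difference of 0.00 (95% interval -0.38 to 0.38). The difference was -0.16 for CHRNA6 (-0.41 to 0.10) and 0.06 for VEGFA (-0.16 to 0.27). Without tubercidin replicate 1 the FOSL2 difference was -0.13, without tubercidin replicate 2 that of CHRNA6 was -0.040, and without AB61 replicate 1 that of VEGFA was -0.016. No gene passed limma's test, 721 genes (5.07%) had an unadjusted p below 0.05, and 6.02% had fully separated arrays against 10% by chance. A missed threshold does not show that the compounds act alike, since the median 95% interval reached 0.28 to either side. CHAC1 stood at -0.86 (-1.30 to -0.42, adjusted p = 0.793) and KCNRG at -0.34 (-0.57 to -0.12). The difference with the smallest p, chosen after the values were seen, was GCNA (-0.75, SE 0.14, 95% interval -1.05 to -0.46, adjusted p = 0.772), and TXNIP, a thioredoxin-interacting protein gene chosen in the same way, stood at -0.97 (-1.41 to -0.54).

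As lists, cholesterol synthesis genes were lower in AB61 than in tubercidin (median -0.22, 12 of 13 fitted below 0, adjusted p = 1.19e-05; adjusted p = 0.343 with an estimated correlation), with HMGCS1 at -0.48 (95% interval -0.89 to -0.06) and INSIG1 at -0.22 (-0.51 to 0.07). Histone genes were lower as well (-0.19, 44 of 50 fitted below 0, 2.41e-10; adjusted p = 0.465 with an estimated correlation). The histone median was -0.07 without AB61 replicate 2, -0.08 without tubercidin replicate 2 and -0.30 without AB61 replicate 3, and the cholesterol median was -0.37 without AB61 replicate 3. In all 14 of 27 lists were lower in AB61, 0 with an estimated correlation or fry, and 6 without AB61 replicate 2 or 8 without tubercidin replicate 2. Fewer lists also shifted after repeated quantile normalization, with the intensity trend removed, or among genes at or above the median level. The count therefore depends on the scaling of the arrays.

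Between AB61 and actinomycin D no gene passed limma's test, 260 genes (1.83%) had an unadjusted p below 0.05, and 4.41% had fully separated arrays against 10% by chance. Cholesterol synthesis genes were lower in AB61 (median -0.23, 12 of 13 fitted below 0, 3 lower adjusted over the list alone, adjusted p = 1.1e-09; adjusted p = 0.0714 with an estimated correlation), with HMGCS1 at -0.60 (95% interval -1.02 to -0.19) and INSIG1 at -0.31 (-0.60 to -0.01), or -0.38 and -0.18 without actinomycin D replicate 2. The list median was -0.35 without AB61 replicate 3. CHRNA6 differed by -0.25 (-0.51 to 0.01), VEGFA by 0.19 (-0.02 to 0.41) and CHAC1 by 0.31 (-0.12 to 0.75). VEGFA was 0.12 without AB61 replicate 1 and CHAC1 0.20 without actinomycin D replicate 2. NF-kB target genes (0.12, adjusted p = 0.0111; adjusted p = 0.593 with an estimated correlation) and ATF4 and integrated stress response genes (0.10, 0.0454; adjusted p = 0.593 with an estimated correlation) were higher in AB61. Both calls ended without AB61 replicate 3 (adjusted p = 0.429 and 0.913) or actinomycin D replicate 1 (0.523 for both), and the ATF4 call also without actinomycin D replicate 2 (0.0858). The NF-kB median was 0.05 without actinomycin D replicate 1. Of 27 lists 12 shifted, 10 lower and 2 higher in AB61, 0 with an estimated correlation or fry, and 4 without AB61 replicate 2. The number was also 4 after repeated quantile normalization and 4 with the intensity trend removed, and it was smaller with array weights.

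Between tubercidin and actinomycin D the ATF4 and integrated stress response genes were higher in tubercidin, by a median of 0.14 (19 of 22 fitted above 0, adjusted p = 5.62e-08), and the call held with the estimate (adjusted p = 0.0316 with an estimated correlation), though not with fry (adjusted p = 0.201). CHAC1, at 8.01 ± 0.20 in tubercidin and 6.84 ± 0.27 in actinomycin D (n = 3), differed most, by 1.17 (SE 0.20, 95% interval 0.74 to 1.61), and was the 1 member past the threshold adjusted over the list alone, while its adjusted p over all genes was 0.853. DDIT3, which encodes the stress transcription factor CHOP, differed by 0.65 (0.21 to 1.09) and ATF3 by 0.28 (-0.04 to 0.61; 0.18 without actinomycin D replicate 1), and neither passed the test. No gene passed limma's test over all genes, 184 genes (1.29%) had an unadjusted p below 0.05, and 6.56% had fully separated arrays against 10% by chance. In all 5 of 27 lists were higher in tubercidin, 1 with an estimated correlation, 0 with fry, and 3 without actinomycin D replicate 1.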

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

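The fit with the intensity trend removed was chosen after the data had been seen, and the other tests in this part were planned. The integrated stress response genes stood out because tubercidin and actinomycin D differed in a direct test, with a list median 0.140 higher in tubercidin, where the medians of all 3 arrays lay above the highest of actinomycin D, -0.22. No single array accounted for it, since the smallest difference in the 6 fits that left out 1 array was 0.110, without actinomycin D replicate 1. With the intensity trend removed the difference was 0.112 and still passed with the preset correlation, which leaves open how much of it follows the intensity range of the arrays. A difference between the compounds in this stress pathway may underlie it, as a hypothesis, since molar dose, uptake and time course were not varied and fry did not call the list (adjusted p = 0.201). Whether CHAC1, which differed most, moved through this pathway was not tested.

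Among 7579 probe sets without a single gene name, 1 was called after AB61, lower than in control (log2 fold change -1.35, SE 0.16, adjusted p = 0.0388). It stood out because these probe sets enter no count of genes, and in the other 5 contrasts 0 of them were called by limma.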

How the results depend on the processing

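With 3 arrays per group, calls near the threshold moved with most settings, while directions mostly held where a setting could change them. For named genes the variance trend, the block, fits of 2 groups, every probe set and the filter on dim genes leave log2 fold changes unchanged. Directions kept under those settings were fixed in advance and carry no evidence. Without background values, dim genes could not be separated from unexpressed ones. Values of named genes were counted over settings other than leaving out 1 array, including fits of 2 groups, which drop the other groups' arrays. Of these, 1511 kept direction and side of the threshold, 240 kept direction and missed the threshold, 56 newly passed and 6 reversed. Of the list values, all from fits of 12 arrays, 255, 46, 0 and 5 did so. In fits that left out 1 array, these counts were 786, 230, 12 and 16 for named genes and 163, 41, 0 and 0 for lists. The default estimation of array weights in limma did not converge, so it was not run and a gene-by-gene estimation replaced it, and the authors' tables give no adjusted p, so their own calls could not be counted. The intensity trend removal, the block in fits of 2 groups or with an estimated correlation, the adjustment of the authors' p-values, the gene-by-gene weights and the pooled comparison were chosen after seeing the data. Except where fewer samples, more probe sets or a stricter threshold were the setting itself, the cause was not tested.

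The counts of changed genes were 24, 13 and 17 for AB61, tubercidin and actinomycin D against control. They became 3, 6 and 2 with each array centred on its median, 14, 4 and 35 with ribosomal protein centring, 193, 116 and 130 with the replicate block, 508, 46 and 539 with array weights, 0, 1 and 1 in fits of only the 2 groups compared, and 1, 4 and 2 with every probe set. Array weights ran from 0.228 on AB61 replicate 3 to 2.45 on AB61 replicate 1 and 4.66 on actinomycin D replicate 2. The counts with array weights therefore lean on few arrays. The AB61 count was 45 among genes at or above the median level, 14 with a variance trend and robust settings, 11 with the block in a fit of 2 groups and 2 from the authors' p-values adjusted here. The actinomycin D count was 7 after repeated quantile normalization, 9 with the block in a fit of 2 groups, 8 from the authors' p-values and 3 with the intensity trend removed, where tubercidin had 6. Direct contrasts gave 1 gene for tubercidin against actinomycin D with the block and 8 for AB61 against actinomycin D with array weights. The other groups did not meet the criterion for a pairing. In the other pairs of groups, deviations of same-numbered arrays correlated at 0.0858 to 0.596 for replicate 1 and 0.224 to 0.498 for replicate 3. For replicate 2 they ran from -0.194 to 0.241. Besides, 11 of the 12 arrays correlated best with an array of their own number. Arrays of the same number thus shared variation in those groups too, least for replicate 2, and the main fits leave it in the residual spread.

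Genes changed at least 2-fold, 1, 2 and 3 in the same order, became 11, 4 and 19 with ribosomal protein centring, 14, 12 and 15 with the block, 25, 5 and 9 with array weights, 0, 0 and 1 in fits of 2 groups and 8, 6 and 8 with the block in such fits. For AB61 they were 5 among genes at or above the median level, and for actinomycin D 1 with median centring and 1 with every probe set. In direct contrasts they were 1 for tubercidin against actinomycin D with the block and 2 for AB61 against actinomycin D with array weights.

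Shifted lists numbered 10, 6 and 12 against control, and 14, 12 and 5 for AB61 against tubercidin, AB61 against actinomycin D and tubercidin against actinomycin D. After repeated quantile normalization AB61 against control had 6 and the direct contrasts 7, 4 and 2, and with the intensity trend removed these were 6 and 5, 4 and 3. Among genes at or above the median level AB61 against tubercidin had 7 and tubercidin against actinomycin D 2, and with array weights AB61 against actinomycin D had 7. With an estimated correlation, with or without the block, the 6 counts were 0, 0, 0, 0, 0 and 1, and with fry 0, 0, 1, 0, 0 and 0.

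For the replicate block, correlations were taken between differences of same-numbered arrays, 1 number at a time, and their means were 0.489 for AB61 and tubercidin, 0.685 for AB61 and actinomycin D and 0.653 for tubercidin and actinomycin D. These are not comparable with correlations of changes averaged over 3 arrays. Over genes called in either comparison the correlations, 0.969, 0.982 and 0.942 in the same order, carry no evidence of likeness, since the genes were chosen for a change against the same controls and no value for unchanged groups was made. With the block the overlap of calls, AB61 and tubercidin, was 77, that of AB61 and actinomycin D 98 and the overlap of calls, tubercidin and actinomycin D, 77, and at an adjusted p below 0.01 they were 0, 0 and 1. The pooled comparison gave 729 genes with the block.

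Over fits that left out 1 array of the groups compared the counts of changed genes ranged from 0 to 98 for AB61, 2 to 33 for tubercidin and 1 to 25 for actinomycin D, and 0 to 0 in each direct contrast. At least 2-fold they ranged from 0 to 12, 1 to 14 and 1 to 14, and 0 to 0 in direct contrasts. Lists ranged from 6 to 14, 5 to 9 and 9 to 11 against control, and from 6 to 12, 4 to 11 and 3 to 6 in direct contrasts. Correlations ranged from 0.435 to 0.738, 0.674 to 0.837 and 0.688 to 0.831, overlaps from 0 to 10, 0 to 13 and 1 to 19, and the pooled count from 27 to 435.

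Directions reversed for 5 called lists and for values of named genes that had not passed. Under ribosomal protein centring the ZNF, mitosis and DNA damage lists after tubercidin were -0.10, -0.070 and -0.033, and the ZNF and mitosis lists after actinomycin D -0.21 and -0.19. For genes, the log2 fold change of MYC, actinomycin D vs control was -0.00076 there, that of MYC after tubercidin -0.016 and that of DDIT3 after tubercidin -0.12. With array weights CDKN1A after AB61 was 0.023 and MYC after tubercidin -0.099, and with median centring FOSL2 in AB61 against tubercidin was -0.036.

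Over fits that left out 1 array, MYC ranged from -0.25 to 0.50 after AB61, from -0.27 to 0.48 after tubercidin and from -0.18 to 0.57 after actinomycin D, lowest without control replicate 3 in each. It was also negative without AB61 replicate 1 (-0.035) and actinomycin D replicate 1 (-0.018). CDKN1A after AB61 ranged from -0.17 to 0.033 (without AB61 replicate 3), and HES1 after actinomycin D from -0.26 to 0.040 (without actinomycin D replicate 3). After tubercidin, DDIT3 ranged from -0.14 (without tubercidin replicate 2) to 0.24 and was -0.056 without control replicate 1. ADK ranged from -0.22 to 0.016 (without tubercidin replicate 3) and was 0.0087 without control replicate 1, and CHAC1 ranged from -0.38 to 0.028 (without control replicate 3). In AB61 against tubercidin, FOSL2 ranged from -0.13 (without tubercidin replicate 1) to 0.078, with -0.043 and -0.019 without AB61 replicates 1 and 3, and VEGFA from -0.016 (without AB61 replicate 1) to 0.11.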

Other observations

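The counts over other splits of the 6 arrays, the simulation with the spread of each group, the pooled comparison and the intensity trend removal were chosen after the results were seen, and the remaining tests were set down before their results. With the 9 treated arrays together against the 3 control arrays, 296 genes passed, 167 higher and 129 lower, and 256 of them had all treated arrays beyond all control arrays. With no vehicle described for the controls, this comparison cannot tell the compounds apart from a vehicle. The genes named here were chosen after their values were seen. NR4A1 fell by 1.84 (SE 0.28, adjusted p = 0.00626) and EGR1 by 1.86 (SE 0.41, adjusted p = 0.0334), together with RGS1 at -1.63 and RGS2 at -1.35, regulators of G-protein signalling (adjusted p = 0.0106 and 0.0231). Also lower were PFKFB3 (-0.93, adjusted p = 0.00363) and PFKFB4 (-1.22, adjusted p = 0.0107), which encode enzymes that set fructose 2,6-bisphosphate levels, and the enolase gene ENO2 (-1.20, adjusted p = 0.0319). The chemokine receptor gene CXCR4 (-0.72, adjusted p = 0.00911), the clock gene PER1 (-0.71, adjusted p = 0.0153) and HEXIM1 (-0.72, adjusted p = 0.0114) were lower, and the interleukin 7 receptor gene IL7R (1.05, adjusted p = 0.0107) and ACKR3 (1.13, adjusted p = 0.0356) were higher. NR4A1 and PFKFB3 passed in each fit that left out 1 array. The others lost the call without control replicate 2, at adjusted p = 0.121 for EGR1, 0.0678 for RGS1, 0.143 for RGS2, 0.0623 for PFKFB4, 0.108 for ENO2, 0.0636 for CXCR4, 0.0678 for PER1, 0.0636 for HEXIM1, 0.0747 for IL7R and 0.145 for ACKR3. They also lost it without control replicate 3, in the same order at adjusted p = 0.0991, 0.0662, 0.128, 0.0509, 0.138, 0.0662, 0.0842, 0.078, 0.0755 and 0.175, where EGR1 stood at -1.02 and ENO2 at -0.74. Without actinomycin D replicate 2 EGR1 (0.0607), ENO2 (0.0592) and ACKR3 (0.0666) missed the threshold, without actinomycin D replicate 1 EGR1 (0.0503) and ACKR3 (0.0507), without tubercidin replicates 1 and 3 EGR1 (0.0559 and 0.0554), and without AB61 replicate 2 ENO2 (0.0523).

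The pooled count was 27 without control replicate 2, 30 without control replicate 3, 146 without actinomycin D replicate 2, 188 and 168 without tubercidin replicates 1 and 3, and 435 without tubercidin replicate 2. Under ribosomal protein centring 8 genes were higher and 299 lower. Of 100 drawn splits of the 12 arrays into 9 and 3, out of 220 possible, 2 gave as many genes as the real one, a share under 0.05. The highest other split called 571, with control replicates 1 and 2 and tubercidin replicate 2 on one side, and shared 24 genes with the 296, which points to a structure of the samples.

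Immediate early genes were lower after AB61, tubercidin and actinomycin D with the preset correlation (adjusted p = 0.382, 0.396 and 0.331 with an estimated correlation), with a wide spread among the control arrays. The smallest covariance of the changes over the list was 0.233, above the highest of simulations of shared controls with equal spread in all groups, 0.126. With the spread of each group 1, 0 and 1 of 100 simulations reached the covariances of the 3 pairs of treatments. The bound of all 3 pairs above the highest was therefore not met. Both sets of simulations drew each gene independently. From control replicate 1 to 3, however, EGR1 rose from 7.49 to 10.69 and NR4A1 from 7.72 to 9.79. The simulations therefore cannot tell how often shared control arrays alone give such values, and that explanation stays open. The spread among controls was 1.77 times that within treated groups in the list median, at the 100th percentile of random lists matched on level. Genes of the random lists were drawn singly and need not vary together as the listed genes do, so the percentile can overstate the evidence. Varying stimulation of the untreated cultures may contribute. A response to the compounds stays open beside it, since the same 3 control arrays enter each comparison.

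Histone genes were lower in AB61 than in tubercidin with the preset correlation (adjusted p = 0.465 with an estimated correlation). The interquartile range of levels was 2.88, 2.72 and 3.06 on AB61 replicates 1, 2 and 3. On arrays of the other groups it lay between 2.94 (actinomycin D replicate 1) and 3.06 (tubercidin replicate 2). Removing the intensity trend left the histone difference at -0.16, against -0.19 before. For this list that argues against an intensity trend common to all genes of an array as the whole cause. Over all lists, fewer shifted between these compounds with the trend removed. Without AB61 replicate 2 the histone difference was -0.072, and without tubercidin replicate 2 it was -0.075, so 1 array of either group could account for much of it. These arrays have the narrowest and the widest interquartile range of all, 2.72 and 3.06. A part of the intensity range in the histone difference therefore stays open, as does a difference between the compounds.

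Slowed elongation would lower long genes more, a hypothesis tested by Spearman's rho of gene span and log2 change over 14205 genes. The values were -0.0127 for AB61, 0.0268 for actinomycin D and 0.0720 for tubercidin, against a bound of -0.05 set in advance. For tubercidin the values without 1 array ran from -0.0287 (without control replicate 2) to 0.162 (without control replicate 3). All stayed above the bound, so the result set in advance for no lowering of long genes was met. Yet the shared control arrays moved rho alike for the other compounds. Without control replicate 3 it was 0.0686 for AB61 and 0.114 for actinomycin D. No value for unchanged groups was made, so the test cannot tell rho for tubercidin apart from differences among the control arrays. Slowed elongation itself was not measured. For AB61 the value was -0.104 without AB61 replicate 3 and -0.0923 without control replicate 2, and for actinomycin D -0.0656 without control replicate 2, so for these compounds the arrays are too few to decide.

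For comparisons of 3 against 3 arrays the 10 splits are too few for a share under 0.05. The numbers of splits with as many genes were 1 for AB61 (24, highest other 5), 2 for tubercidin (13, highest other 45) and 1 for actinomycin D (17, highest other 0) against control. Each of these numbers includes the real split. They were 10 for AB61 against tubercidin (0, highest other 3), 10 for AB61 against actinomycin D (0, highest other 564) and 10 for tubercidin against actinomycin D (0, highest other 0). Every split reaches a real count of 0, so the numbers for these direct contrasts test nothing. The split with 45 genes set control replicates 1 and 2 and tubercidin replicate 2 apart, and that with 564 genes set AB61 replicates 1 and 2 and actinomycin D replicate 1 apart, which points to a structure of the samples beyond the treatments.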
